A study of Oryza sativa with 18 samples.

How the data were processed

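RNA of field-grown rice grains was sequenced by the authors as poly(A)-selected paired-end libraries on an Illumina HiSeq instrument. Changhui T025, Wufeng B and their hybrid WFYT025 were sampled at day 1 and day 10 after anthesis, with 3 libraries per group. The labels do not say whether replicates are separate plants. The submitters name HISAT, StringTie and edgeR with build IRGSP-1.0, without versions. The deposited table gives estimated counts (expected counts) per MSU gene model and library as whole numbers, per the file headers. It also gives deposited FPKM, fragments per kilobase of transcript scaled to mapped fragments, with 0 written as 0.0001. Above 500 counts, 100% of gene-library pairs held a fixed ratio of count to FPKM within 1%, and low counts piled up at 4, 8 and 12, so 1 fragment counts about 4. Another 108 columns, whose names match no sample here, were not used.

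The design, set before the data were examined, named limma on FPKM as the test or, if counts were present as here, edgeR. It also set the comparisons, filters, naming rule and most alternatives. Genes passing filterByExpr in edgeR 4.0.16 (26997 of 42004) were scaled by TMM (factors 0.396 to 1.94) and fitted with a robust quasi-likelihood model. One fit covered 18 libraries in 6 groups, with 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The mid-parent was the mean of both parents on the log2 scale, and the interaction compared the hybrid's difference from it between days. Other tools were R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

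Gene lists numbered 16, of which 14 with at least 5 tested genes entered limma's camera in 168 tests corrected together, with a preset correlation of 0.01 and, second, an estimated one. Of 862 members, 110 were listed by identifier beforehand, and the rest were drawn from the table's descriptions after the annotation text, but before any test value, was seen. Gene names and functions come from the table's descriptions. List medians were also computed with genes absent from a group set to their bound. Against a group with 0 counts a fold was given as a lower bound at 12 deposited counts (3 fragments) over the group, and groups with 1 to 3 fragments were given as levels only. KEGG terms of 10 to 500 genes (127 terms, 1524 tests) were tested in the same way, and 59 of the tests passed by camera, 0 with an estimated correlation (adjusted p at least 0.793). Against the mid-parent at day 1 these were Ribosome (median 0.57, camera adjusted p = 1.31e-19), Photosynthesis (-1.09, 0.00435) and Glutathione metabolism (-0.48, 0.00753).

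The naming rule took, per comparison, called genes with an informative description, at least 5 normalised FPKM in the higher group and no overlap between the libraries compared (for the mid-parent, the same sign in every hybrid library; no such condition for the interaction). Chance alone gives no overlap in 10% of genes for 3 against 3. The 8 largest changes each way were taken, with up to 4 called and 2 uncalled members per list. Grain size genes and endosperm regulators were eligible in any comparison. Among the genes the rule allows, those named in the text were picked after their values were seen, so shares of calls kept are given over all 650 called genes of the rule. Member counts of lists are printed for the stage and the day 1 mid-parent comparisons and where a list passed with 0 genes called. Elsewhere they were left out for length, after their values were seen.

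Methods were tested on simulated data with 200 changed genes per comparison. For the parents at day 1, edgeR recovered 3% of 1.5-fold, 11.9% of 2-fold and 43.9% of 4-fold changes, with 2.5% of calls false. For the hybrid against the mid-parent at day 1 these were 0%, 17.9% and 37.9% with 2.6% false (5% with the linear mid-parent), and for the hybrid between days 3%, 7.5% and 40.9% with 2.9% false. In the same data 16.7% to 46.5% of limma calls and 32% to 43.5% of DESeq2 calls were false. Lists seeded with changed genes passed limma's camera in all 3 comparisons, and control lists did not. Within groups the lowest chi-square per degree of freedom between libraries was 6.3, above counting error.

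Replicate numbers were checked for pairing by correlating deviations from group means. Over 15 pairs of groups r ran from -0.09 to 0.24, and the parents at day 1 alone had all 3 above 0.1 before rounding (0.12, 0.1 and 0.22), with 2071 genes called with a replicate block against 2412 without. Samples were treated as unpaired. Alternatives covered filters, scaling, tests, pseudocounts, the mid-parent's definition, the groups in the fit, a replicate block and the omission of each library.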

Results

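Whole grains of the rice hybrid WFYT025 and of its parents, Changhui T025 (Changhui) and Wufeng B, were compared at day 1 and day 10 after anthesis, at the start of grain growth and during filling. Each of the 6 cultivar-by-day groups held 3 libraries (reps 1 to 3). Library totals ranged from 39805756 to 88520724 deposited counts, in which 1 fragment counts about 4. Of 42004 annotated genes, 26997 were tested. Expression levels are CPM, counts relative to the TMM-scaled library total, given as mean ± SD. Changes are log2 ratios ± an approximate standard error (ratio over the root of F) from edgeR's quasi-likelihood fit of 18 libraries. Its Benjamini-Hochberg adjusted p is padj. Groups-only fits hold only the groups compared, and linear and weighted mid-parents are the log2 of the linear mean and a mean with weights of 2 for Wufeng B and 1 for Changhui. List padj values come from limma's camera with a preset correlation, and p_e is the adjusted p with an estimated correlation. Where another scaling moves a called list's median by over 1.5 times, that median follows as totals (library totals), FPKM (unscaled) or quantile (quantile-normalised). Calls within a list adjust over its genes alone. Gene identifiers are those of the table, on the rice build IRGSP-1.0.

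Day of sampling separated the libraries most. The first principal component, with 63.9% of the variance, parted day 1 from day 10, and the second, with 8.7%, ordered the cultivars with the hybrid between its parents. Storage protein genes took between 37.0% and 51.5% of all counts at day 10 and at most 0.095% at day 1. At day 1, rep 2 of Wufeng B stood apart from its group on the first component, at -163.8 against -236 and -224.3, near the hybrid libraries at -178.4 to -123.8. Changhui day 1 rep 3 held 5.87% of its counts in photosynthesis genes, against 1.02% and 1.18% in the other Changhui libraries.

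**Figure D1:**
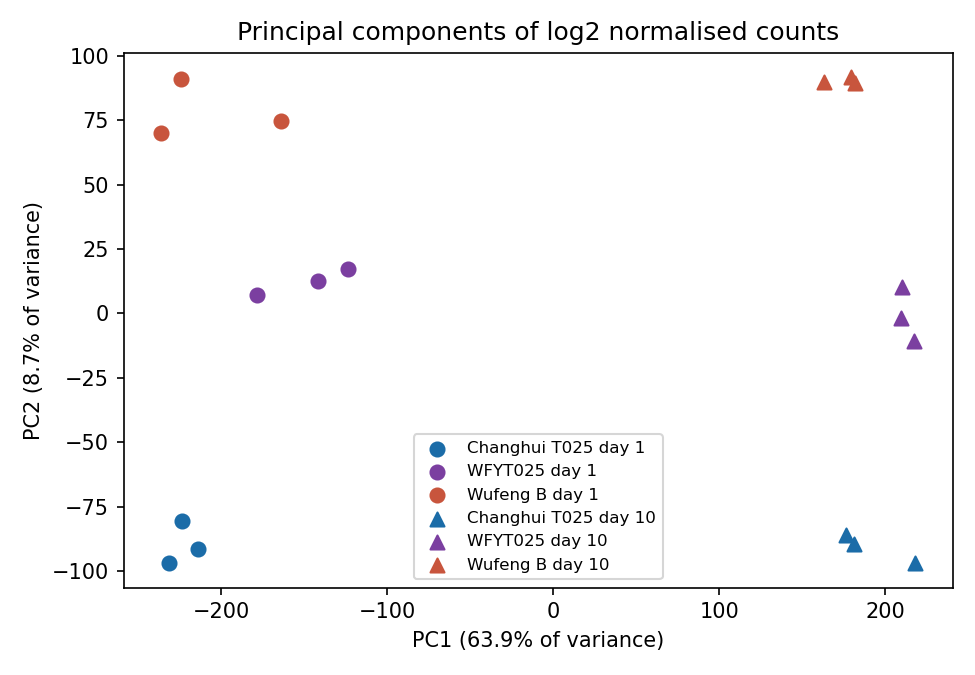
Principal components of log2 CPM of the tested genes, with 1 point per library, colours for cultivars, circles for day 1 and triangles for day 10. The horizontal axis (63.9% of the variance) separates day 1 from day 10, and the vertical axis (8.7%) places the hybrid between its parents.

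The change from day 1 to day 10 showed what grain filling added to and removed from the transcriptome of Changhui. All 40 tested storage protein genes rose (list median 12.07 on the log2 scale, 11.81 with genes at 0 set to their bound, padj = 3.15e-21, p_e = 0.771). The prolamin genes PROLM12 (LOC_Os05g26480) and PROLM9 (LOC_Os05g26377), which encode alcohol-soluble seed proteins, went from 0 counts to 2830 ± 427 and 3290 ± 464 CPM, at least 72500-fold and 84500-fold higher. A glutelin gene (LOC_Os02g15150) rose by 15.27 ± 1.69 to 53100 ± 8630 CPM. Members of these families are nearly identical in sequence, so the values of single members are uncertain. The seed allergen gene RAL3 (LOC_Os07g11360) rose by 11.69 ± 1.25.

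In starch synthesis, 15 of 24 tested genes rose and 7 fell in Changhui, with 22 called also within the list (median 2.50, totals 0.89, FPKM 0.86, padj = 0.00128, p_e = 0.771). A starch synthase gene (LOC_Os06g04200) rose by 12.35 ± 2.25 and soluble starch synthase 2-3 (LOC_Os06g12450) by 10.90 ± 2.01. A 1,4-alpha-glucan-branching enzyme gene (LOC_Os02g32660), which adds branch points to amylopectin, rose by 8.70 ± 1.39. The alpha-glucan phosphorylase isozyme gene (LOC_Os03g55090) rose by 8.17 ± 0.78. Sucrose synthase, which splits imported sucrose, rose at LOC_Os07g42490 by 8.40 ± 1.73 and at LOC_Os03g22120 by 5.42 ± 0.32. Among 47 embryo and aleurone markers, 34 rose and 10 fell (44 within the list, median 5.77, FPKM 1.96, quantile 2.72, padj = 1.59e-05, p_e = 0.771). A late embryogenesis abundant group 1 gene (LOC_Os06g21910) went from 0 to 46.8 ± 22.6 CPM, at least 1200-fold, and an oleosin gene (LOC_Os09g15520), coding for an oil body protein, from 0.00491 ± 0.00851 to 66.9 ± 17.9 CPM.

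Several genes present at day 1 in Changhui were at 0 at day 10. A nodulin MtN3 family gene (LOC_Os05g51090), a family that includes sugar transporters, stood at 234 ± 231 CPM at day 1 and at 0 at day 10, at least 2430-fold lower. ROPGEF7 (LOC_Os01g48410) went from 192 ± 189 CPM to 0 (at least 1990-fold lower), a pectate lyase gene (LOC_Os06g05209) from 168 ± 164 to 0 (at least 1740-fold), a pectinesterase gene (LOC_Os07g49100) from 138 ± 139 to 0 (at least 1430-fold) and an expansin gene (LOC_Os10g40090) from 53.8 ± 46.9 to 0 (at least 559-fold). At day 1 the MtN3 gene stood at 473, 217 and 12.7 CPM and ROPGEF7 at 386, 182 and 7.84 in replicates whose pollen and anther marker genes held 0.276%, 0.166% and 0.071% of counts. That list had a median change of -1.79 (-1.12 at the bound, padj = 0.354) and no call. Of 68 photosynthesis genes 2 rose and 56 fell (61 called within the list), with a median of -4.58 (-4.49 at the bound, padj = 7.67e-07, p_e = 0.787). The genes that rose numbered 1 without day 1 rep 1, 2 or 3 or day 10 rep 2 or 3.

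The MADS-box genes OsMADS6 (LOC_Os02g45770, change -4.49 ± 0.27) and OsMADS29 (LOC_Os02g07430, -2.19 ± 0.29), both transcription factors of seed development, fell in Changhui. So did the SBP-box genes OsSPL13 (LOC_Os07g32170, -5.38 ± 0.65) and OsSPL16 (LOC_Os08g41940, -4.68 ± 1.07), known as grain size genes. Kinesin-13A (LOC_Os05g06280), a microtubule motor gene of the grain size list, rose by 1.30 ± 0.14 (padj = 1.67e-06) after TMM scaling, but its sign reversed to -0.25 on unscaled FPKM and to -0.30 on library totals. GIGANTEA (LOC_Os01g08700, -1.68 ± 0.26) and a response regulator gene (LOC_Os07g49460, -3.20 ± 0.21) of the clock list fell. Of 134 cytosolic ribosomal protein genes 90 rose and 8 fell (91 and 9 within the list), for example S5 (LOC_Os11g29190) by 2.68 ± 0.42. Their median of 0.80 (padj = 3.59e-06, p_e = 0.797) turned to -0.78 on library totals and to -0.74 on unscaled FPKM (quantile 0.35), and the call was lost on unscaled FPKM (0.395) and quantile values (0.144).

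The cell cycle list passed the test in Changhui with 25 genes higher and 7 lower of 62 (25 and 5 within the list, median 0.57, 0.65 at the bound, padj = 0.0456, p_e = 0.797), with the median at -0.96 on library totals and -0.75 on unscaled FPKM. Its call was lost without day 1 rep 3 (padj = 0.0593) and day 10 rep 1 (0.0586) or 2 (0.0508), on unscaled FPKM (0.32) and with a pseudocount of 0.1 (0.0718), and without day 1 rep 2 the genes lower numbered 4. Heat shock proteins, with 40 higher and 25 lower of 102 (41 and 25 within the list), had a median of 0.25 (0.38 at the bound, padj = 0.0398, p_e = 0.771) that turned to -1.26 on library totals and -0.95 on unscaled FPKM (quantile 0.39). This call was lost without day 1 rep 1 (padj = 0.0796) and day 10 rep 2 (0.0516) or 3 (0.0523), on unscaled FPKM (0.262) and quantile values (0.0766) and with a pseudocount of 0.1 (0.068).

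Wufeng B filled its grains with the same gene classes: all 40 storage protein genes rose (median 11.79, padj = 3.83e-21, p_e = 0.771). PROLM12 went from 0 to 875 ± 120 CPM, at least 23500-fold. Starch synthesis genes rose in 15 cases and fell in 5 of 24 (20 called within the list, median 2.34, totals 0.84, FPKM 0.83, padj = 6.7e-05, p_e = 0.771), and the genes lower numbered 3 without day 1 rep 3 or day 10 rep 3. The branching enzyme gene LOC_Os06g51084 rose by 8.04 ± 0.41 to 22400 CPM. The large subunit of glucose-1-phosphate adenylyltransferase (LOC_Os08g25734), the enzyme that makes ADP-glucose for starch, rose by 6.32 ± 0.63. A phosphofructokinase gene (LOC_Os09g30240) went from 0 to 21.3 ± 1.92 CPM (at least 571-fold) and a sulfate transporter gene (LOC_Os01g41050) from 0 to 26.4 ± 3.77 CPM (at least 707-fold). An oleosin gene (LOC_Os03g49190) rose by 12.50 ± 1.04 and RAL3 by 12.61 ± 1.29, and 30 of 47 embryo and aleurone markers rose and 7 fell (37 within the list, median 4.82, FPKM 2.19, quantile 3.05, padj = 3.14e-06, p_e = 0.771).

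OsMADS6 (-3.70 ± 0.26), OsSPL13 (-4.86 ± 0.63), OsSPL16 (-4.63 ± 1.04) and GIGANTEA (-1.73 ± 0.26) fell in Wufeng B. Kinesin-13A (LOC_Os05g06280) rose by 1.03 ± 0.14 (padj = 1.98e-05), again reversed to -0.42 on unscaled FPKM and -0.48 on library totals. The small chain of ribulose bisphosphate carboxylase (LOC_Os12g19381, -5.02 ± 1.04), the carbon-fixing enzyme, fell with 48 other photosynthesis genes of 68 while 1 rose (54 called within the list, median -3.18, -3.16 at the bound, padj = 1.77e-05, p_e = 0.787). Without day 1 rep 3, 2 rose and 37 fell. MCM9 (LOC_Os06g11500, -4.84 ± 0.52), of the replication helicase family, and ribosomal protein S9-1 (LOC_Os03g26229, -4.56 ± 0.86) fell, although the ribosomal list as a whole had 16 genes higher, 26 lower and a median of 0.01 (padj = 0.966), turning to -1.50 on library totals.

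The hybrid raised the 40 storage protein genes too (median 11.48, 11.46 with genes at their bound, padj = 9.19e-22, p_e = 0.771). PROLM12 reached 3850 ± 1260 CPM from 0, at least 114000-fold. The thionin genes THION9 (LOC_Os06g32240) and THION3 (LOC_Os06g31890), which encode small antimicrobial proteins, went from 0 to 176 ± 71.2 and 141 ± 53.6 CPM (at least 5210-fold and 4180-fold). The MOTHER OF FT-like gene osMFT2 (LOC_Os01g02120) went from 0 to 38.6 ± 26.2 CPM (at least 1150-fold). Starch synthesis genes rose in 13 cases and fell in 4 of 24 (17 within the list, padj = 0.00497, p_e = 0.771), with a median of 1.84 that turned to -0.20 on library totals and -0.16 on unscaled FPKM (quantile 1.09) and a call lost on quantile values (0.154). The branching enzyme gene LOC_Os06g51084 rose by 7.92 ± 0.41, starch synthase LOC_Os06g04200 by 5.71 ± 1.73 (lost on quantile values, padj = 0.0768), oleosin LOC_Os03g49190 by 10.94 ± 0.98 and RAL3 by 11.92 ± 1.26. Embryo and aleurone markers rose in 31 and fell in 6 of 47 cases (37 within the list, median 5.43, totals 3.36, FPKM 2.29, quantile 3.47, padj = 1.33e-05, p_e = 0.771).

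CSLF2 (LOC_Os07g36690), a cellulose synthase-like gene for mixed-linkage glucan of cell walls, went from 48.6 ± 41.5 CPM to 0 in the hybrid (at least 425-fold lower), and the MtN3 gene LOC_Os05g51090 from 41.4 ± 30.0 to 0 (at least 362-fold lower). OsMADS6 (-3.90 ± 0.27), OsSPL16 (-4.91 ± 1.15), a chlorophyll A-B binding protein gene (LOC_Os04g59440, -4.87 ± 0.51) and ribosomal protein S17 (LOC_Os03g01900, -1.78 ± 0.20) fell, and OsSPL13 passed from 8.06 ± 2.13 to 0.127 ± 0.113 CPM. Kinesin-13A (LOC_Os05g06280) rose by 0.71 ± 0.14 (padj = 0.000501), reversed to -1.24 on unscaled FPKM and -1.33 on library totals and lost on quantile values (0.154). Photosynthesis genes fell in 40 and rose in 2 of 68 cases (42 within the list, median -3.28, -3.22 at the bound, totals -5.27, padj = 4.79e-05, p_e = 0.797), a call lost on unscaled FPKM (0.395), and those that rose numbered 1 without day 1 rep 1, 2 or 3 or day 10 rep 1 or 2.

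edgeR called 17171 genes between the days in Changhui (7972 higher, 9199 lower at day 10), 16168 in Wufeng B (7212 and 8956) and 15729 in the hybrid (7103 and 8626), at adjusted p below 0.05. In all 3 cultivars 4985 genes were called higher and 5946 lower, and 411 were called in opposite directions in a pair of cultivars. The median change of all genes was -0.167, -0.248 and -0.242. On library totals without TMM it moved to -1.76, -1.74 and -2.27, and the splits became 2217 higher and 18260 lower, 1903 and 18431, and 1373 and 20730. On unscaled FPKM they were 1990 and 16482, 1950 and 16740, and 1302 and 18601, and with limma on log2(FPKM + 1) 5692 and 10058 in Changhui and 5263 and 9799 in the hybrid. Among all genes named by the rule set before the data were examined, 88.9%, 84.7% and 83.3% of calls in these 3 comparisons held under every alternative tried.

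**Figure D2:**
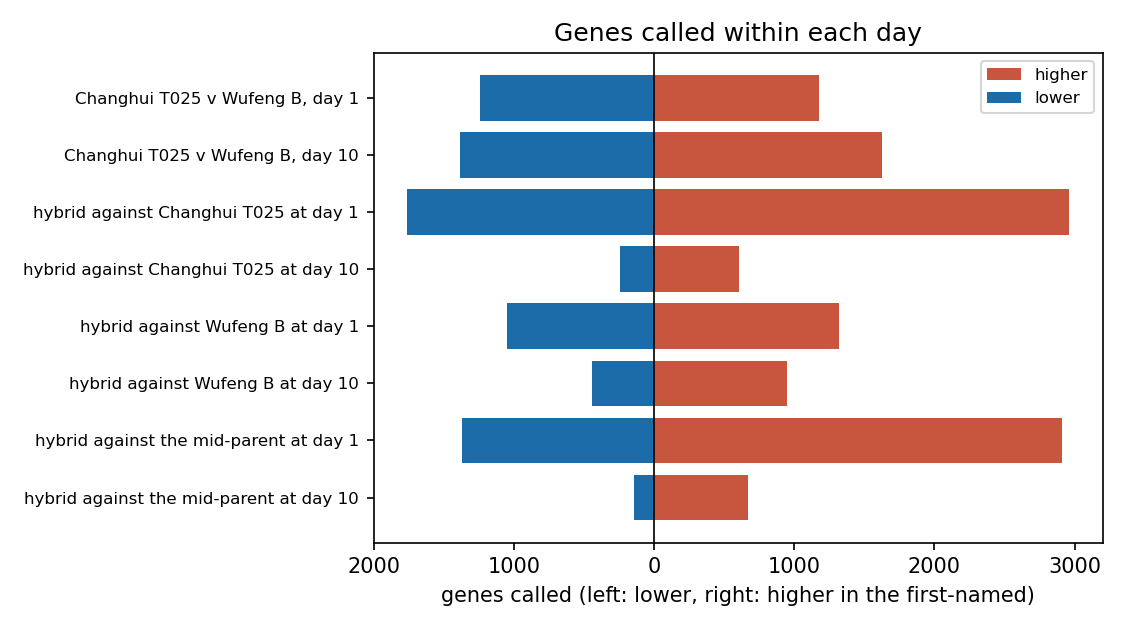
Genes called at adjusted p below 0.05 within each day, with bars to the right for genes higher and to the left for genes lower in the first-named group, on a linear axis through 0. Counts run from 814 genes (mid-parent, day 10) to 4726 (Changhui, day 1).

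Among the largest differences of the parents at day 1 were genes expressed in only 1 of them. In Changhui a gene annotated as circumsporozoite protein (LOC_Os04g40190) stood at 96.2 ± 0.494 CPM and in Wufeng B at 0, at least 2580-fold apart. An O-methyltransferase gene (LOC_Os05g43930) stood at 38.2 ± 8.40 against 0.0129 ± 0.0224 CPM, the SHR5-receptor-like kinase gene (LOC_Os04g52606) at 28.6 ± 12.8 against 0.0248 ± 0.0215 CPM, and the lipid transfer protein gene LTPL158 (LOC_Os10g36110) was higher in Changhui by 6.68 ± 0.53. In the other direction, an exo70 exocyst subunit gene (LOC_Os07g10940) stood at 27.0 ± 9.63 CPM in Wufeng B against 0, at least 692-fold. Flavonoid genes followed: dihydroflavonol-4-reductase (LOC_Os01g44260) at 24.5 ± 5.87 CPM in Wufeng B against 0 (at least 627-fold) and leucoanthocyanidin dioxygenase (LOC_Os01g27490) at 47.6 ± 10.5 against 0.0219 ± 0.0318 CPM.

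A hypersensitive-induced reaction protein gene (LOC_Os06g04399) stood at 17.4 ± 1.77 CPM in Wufeng B and 0.0192 ± 0.0333 in Changhui. A staphylococcal nuclease homologue (LOC_Os12g15314) and a proteasome maturation factor gene (LOC_Os03g38720) were at 19.3 ± 2.88 and 5.90 ± 0.732 CPM in Wufeng B and at 0 in both Changhui and the hybrid (at least 495-fold and 152-fold against Changhui), the former lost with DESeq2 (padj = 0.0587). The trypsin inhibitor gene BBTI5 (LOC_Os01g03360) was lower in Changhui (-6.48 ± 1.04, lost in the groups-only fit, padj = 0.0569), as was a response regulator gene (LOC_Os02g40510, -0.99 ± 0.11). A nodulin MtN3 gene (LOC_Os12g29220) was higher by 2.96 ± 0.31, and a starch synthase gene (LOC_Os07g22930) by 1.79 ± 0.37 (lost in the groups-only fit, padj = 0.12).

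Several day 1 differences of the parents rested on Wufeng B rep 2. Sucrose synthase LOC_Os07g42490 (change -5.96 ± 1.55, padj = 0.0257) stood at 4.81, 1150 and 3.49 CPM in the Wufeng B replicates and between 5.72 and 6.96 in Changhui, and its sign reversed to 0.57 without Wufeng B rep 2. Soluble starch synthase 2-3 (LOC_Os06g12450, -6.36 ± 1.68, padj = 0.0277) stood at 0.408, 156 and 0.291 CPM and reversed to 0.84. Both calls were lost also without Changhui rep 1 (padj = 0.0832 and 0.1), 2 (0.097 and 0.0751) or 3 (0.0735 and 0.08), with replicate number as a block (0.0907 and 0.0728), in the groups-only fit (0.241 and 0.25) and in 5 limma settings (0.254 to 0.362). Sucrose use and sugar transport genes had a list median of 0.40 (totals 0.25, FPKM 0.17, quantile 0.17, padj = 0.0465, p_e = 0.771), a call lost without Changhui rep 3 (0.0649) and Wufeng B rep 1 (0.088) or 2 (0.0592), on quantile values (0.125) and with a pseudocount of 0.1 (0.0891).

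Ribosomal protein genes had a median of -0.35 (padj = 1.53e-05, p_e = 0.797), lost without Wufeng B rep 2 (0.239). Ribosomal protein L27a-3 (LOC_Os02g07890) was lower by -0.91 ± 0.21 (padj = 0.0118), lost without Changhui rep 2 (0.0613) and in the groups-only fit (0.138). Cell cycle genes had a median of -0.19 (totals -0.34, FPKM -0.30, padj = 0.0414, p_e = 0.797), lost without Changhui rep 3 (0.127) or Wufeng B rep 2 (0.441), on unscaled FPKM (0.0904) and quantile values (0.141).

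Between the parents at day 1 edgeR called 2412 genes, 1173 higher and 1239 lower in Changhui, and 1552 without Changhui rep 2, 1099 in the groups-only fit and 4117 with DESeq2. On library totals the split was 725 higher and 1364 lower (median of all genes -0.14). Of the genes named by the rule, 40.4% of calls held under every alternative.

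At day 10 the parents differed in seed storage genes as well as in genes with counts in 1 parent only. The glutelin gene LOC_Os02g15150 reached 53100 ± 8630 CPM in Changhui and 672 ± 123 in Wufeng B (6.31 ± 1.22), and the prolamin genes PROLM27 (LOC_Os12g16880, 6.33 ± 1.04) and PROLM12 (1.69 ± 0.29) were also higher in Changhui, all 3 within near-identical families. Storage protein genes had a median of 1.18 (quantile 0.63, padj = 0.000287, p_e = 0.787). The SHR5-receptor-like kinase gene stood at 57.9 ± 8.85 CPM against 0 (at least 633-fold higher in Changhui), the F-box gene OsFBX14 (LOC_Os01g37260) at 16.4 ± 0.613 against 0 (at least 180-fold), and an acyl-CoA dehydrogenase domain gene (LOC_Os06g23870) was higher by 9.22 ± 0.47. Of the parents, Wufeng B alone had counts of the hypersensitive-induced reaction gene LOC_Os06g04399 (22.2 ± 0.842 CPM, at least 231-fold), a glycine-rich cell wall protein gene (LOC_Os03g07270, 16.4 ± 1.38, at least 171-fold) and the PR5-like gene csAtPR5 (LOC_Os07g30280, 9.85 ± 0.965, at least 102-fold).

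OsMADS29 (-1.91 ± 0.29) was lower in Changhui, while MCM9 (3.70 ± 0.49), ribosomal protein S3a (LOC_Os02g18550, 1.33 ± 0.17) and the MtN3 gene LOC_Os12g29220 (1.72 ± 0.31) were higher. Ribosomal protein genes had a median of 0.48 (totals 0.23, FPKM 0.22, quantile 0.29, padj = 1.23e-11, p_e = 0.771). S5 (LOC_Os11g29190, 1.35 ± 0.40, padj = 0.0432) lost its call without any library but Changhui rep 1 (padj = 0.12 to 0.169), on library totals (0.0973), without the count filter (0.0505), with a block (0.0696) and in 5 limma settings (0.0617 to 0.173). Branching enzyme 2 (LOC_Os04g33460, -1.01 ± 0.26, padj = 0.0188) lost its call without Changhui rep 1 (0.0765) or 2 (0.0841) or Wufeng B rep 2 (0.111). Photosynthesis genes had a median of -0.98 (-0.94 at the bound, quantile -0.63, padj = 0.000421, p_e = 0.797) with 0 of 68 called by edgeR, over all genes or within the list, and 2 lower without Changhui rep 3.

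The count at day 10 was 3013 genes, 1629 higher and 1384 lower in Changhui, and 1852 and 1984 without Wufeng B reps 2 and 3, 5210 in the groups-only fit and 4593 with DESeq2. Library totals gave 828 higher and 2245 lower (median of all genes -0.23) and unscaled FPKM 618 and 1679, and 69.6% of the rule's calls held under every alternative.

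At day 1 the hybrid carried more transcript of several starch synthesis genes and of 1 sucrose synthase gene than Changhui. Sucrose synthase LOC_Os07g42490 stood at 1760 ± 768 CPM against 6.18 ± 0.679 (8.15 ± 1.71, padj = 0.00602). Soluble starch synthase 2-3 was higher by 9.19 ± 1.89, starch synthase LOC_Os06g04200 by 6.97 ± 1.83, branching enzyme LOC_Os02g32660 by 5.42 ± 1.20 and the adenylyltransferase large subunit LOC_Os01g44220 by 4.79 ± 1.10. Starch synthesis genes had a median of 0.53 (padj = 0.00146, p_e = 0.771). LOC_Os06g04200 lost its call without Changhui rep 3 (padj = 0.0563) or hybrid rep 2 (0.0505).

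Ribosomal protein genes had a median of 0.94 (padj = 1.78e-42, p_e = 0.771), with S10 (LOC_Os01g73160, 2.04 ± 0.34) and L32 (LOC_Os09g32500, 1.84 ± 0.30) among them. Cell cycle genes had a median of 0.46 (padj = 3.99e-05, p_e = 0.771), and MCM2 (LOC_Os11g29380), a subunit of the replication helicase, was higher by 3.04 ± 0.63. Core histones had a median of 0.74 (padj = 0.000221, p_e = 0.787).

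Embryo and aleurone markers had a median of 0.77 (0.47 at the bound, padj = 0.00844, p_e = 0.771), and an oleosin gene (LOC_Os06g27910) was higher by 4.84 ± 0.83. The list call was lost without hybrid rep 1 (padj = 0.115) and, with medians of 0.20 and 0.09, on unscaled FPKM (0.111) and quantile values (0.175). Storage proteins had a median of 0.60 (FPKM 1.14, padj = 0.000421, p_e = 0.787) with 0 of 40 called, over all genes or within the list, and 1 higher without Changhui rep 2 or hybrid rep 1. That call was lost without Changhui rep 1 (0.334). Sucrose use and sugar transport had a median of -0.56 (FPKM -0.37, padj = 0.0414, p_e = 0.771), lost without Changhui rep 3 (0.0545) or hybrid rep 2 (0.0992), with replicate number as a block (0.061), on unscaled FPKM (0.0932) and quantile values (0.125) and with a pseudocount of 0.1 (0.166).

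Seed defence and allergen genes had a median of 0.99 (quantile 0.56, padj = 0.0457, p_e = 0.779), lost without Changhui rep 1 (0.262) or hybrid rep 3 (0.094), on unscaled FPKM (0.0951) and quantile values (0.0892) and with a pseudocount of 0.1 (0.071). The Kunitz inhibitor gene KUN1 (LOC_Os04g44470) was higher by 5.73 ± 1.17 and the allergen gene RAL6 (LOC_Os07g11510) by 4.14 ± 1.23 (padj = 0.0317), the latter lost without any library but hybrid rep 1 (padj = 0.0503 to 0.0925). Photosynthesis genes had a median of -1.28 (FPKM -0.71, padj = 0.000255, p_e = 0.797), lost without Changhui rep 3 (0.552), the library with the high photosynthesis share.

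The exo70 gene LOC_Os07g10940 stood at 24.6 ± 7.25 CPM in the hybrid against 0 in Changhui (at least 633-fold), a basic helix-loop-helix gene (LOC_Os02g34320) at 10.9 ± 6.92 (at least 280-fold) and a response regulator gene (LOC_Os04g28120) at 7.15 ± 3.1 (at least 184-fold). Lower in the hybrid were a glutathione S-transferase gene (LOC_Os01g27210, -3.53 ± 0.76), a response regulator gene (LOC_Os03g17570, -0.85 ± 0.19), a UDP-glucosyl transferase domain gene (LOC_Os09g34250, -3.89 ± 0.99, padj = 0.0159), a decarboxylase gene (LOC_Os08g04560, -6.53 ± 1.60, padj = 0.0131) and the clock gene ELF3 (LOC_Os06g05060, -0.82 ± 0.21, padj = 0.0148). Without Changhui rep 3 the transferase and decarboxylase calls were lost (0.118 and 0.135), as they were without hybrid rep 2 (0.08 and 0.0714). The transferase call was lost also without hybrid rep 3 (0.0549), and that of ELF3 without hybrid rep 2 (0.0847). Kinesin-13A was higher by 0.47 ± 0.14 (padj = 0.0325), lost without Changhui rep 2 (0.0816) or 3 (0.103) or hybrid rep 2 (0.18) or 3 (0.0512). The groups-only fit ended the calls of RAL6 (padj = 0.0841), the S-transferase (0.093), LOC_Os03g17570 (0.0964), the UDP-glucosyl transferase (0.0719), the decarboxylase (0.0671) and Kinesin-13A (0.0965). Wufeng B rep 2 and Changhui rep 3 left out together ended the last 3 (0.096, 0.084 and 0.0599), library totals ELF3 (0.07) and Kinesin-13A (0.06), and quantile values the decarboxylase (0.053).

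edgeR called 4726 genes in this comparison, 2962 higher and 1764 lower in the hybrid, with 1743 called without hybrid rep 2 2814 without Changhui rep 2, 2890 in the groups-only fit and 7152 with DESeq2. Library totals gave 2709 higher and 761 lower, limma on log2(FPKM + 1) 2964 and 3264, and a filter at a mean of 5 FPKM 2297 and 2109. The median of all genes was -0.147, and 39.7% of the rule's calls held under every alternative.

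Against Wufeng B at day 1, the hybrid differed in genes at 0 counts in 1 of the cultivars and in ribosomal protein genes. The circumsporozoite protein gene LOC_Os04g40190 stood at 56.4 ± 16.8 CPM against 0 (at least 1510-fold higher), ribosomal protein S17 (LOC_Os04g52361) was higher by 5.62 ± 0.67, the glutelin gene LOC_Os02g15150 by 6.12 ± 1.25 and LTPL158 by 4.67 ± 0.48. A cycloartenol synthase gene (LOC_Os11g35710) stood at 25.4 ± 6.60 CPM in Wufeng B against 0 in the hybrid (at least 752-fold lower). WRKY112 (LOC_Os09g09630, -8.89 ± 1.03) and a glycosyl hydrolase family 17 gene (LOC_Os01g71380, -9.52 ± 1.21), a family of beta-glucanases, were lower too. Ribosomal protein genes had a median of 0.60 (padj = 1.61e-24, p_e = 0.771).

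S10 (1.53 ± 0.33, padj = 0.0139) and L32 (1.37 ± 0.30, padj = 0.0146) were among them and lost their calls without hybrid rep 2 (0.0739 and 0.0807) or Wufeng B rep 1 (0.0652 and 0.0706) or 3 (0.0672 for both). Cyclin-dependent kinases B1-1 (LOC_Os01g67160, 1.58 ± 0.34, padj = 0.013) and B2-1 (LOC_Os08g40170, 1.54 ± 0.43, padj = 0.0411), which act in mitosis, were higher. B1-1 was lost without hybrid rep 2 (0.0771) or Wufeng B rep 1 (0.0576), and B2-1 without hybrid rep 2 (0.243) or 3 (0.0526) or Wufeng B rep 1 (0.143) or 3 (0.144). The cell cycle list had a median of 0.36 (padj = 0.0308, p_e = 0.797), lost without hybrid rep 2 (0.306) or Wufeng B rep 1 (0.0505) or 3 (0.173).

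Core histones (median 0.54, padj = 3.64e-05, p_e = 0.771) and starch synthesis genes (0.71, padj = 0.00478, p_e = 0.771) passed the list test against Wufeng B. Of 24 starch genes 0 were called, over all genes or within the list, 3 higher without hybrid rep 1, and 12 higher and 1 lower without Wufeng B rep 2. Storage proteins had a median of 1.08 (padj = 0.000168, p_e = 0.787), among them PROLM11 (LOC_Os05g26460, 2.71 ± 0.76, padj = 0.0403), which lost its call without any library but Wufeng B rep 2 (padj = 0.0651 to 0.143). Embryo and aleurone markers had a median of 0.57 (FPKM 0.16, quantile 0.11, padj = 0.0414, p_e = 0.779), lost without hybrid rep 1 (0.367) or Wufeng B rep 1 (0.0828) or 2 (0.0857) and on quantile values (0.167).

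Photosynthesis genes had a median of -1.02 (padj = 0.000208, p_e = 0.797) with 0 of 68 called by edgeR, over all genes or within the list, and 1 lower without Wufeng B rep 2. The clock list had a median of -0.41 (padj = 0.0133, p_e = 0.771), lost without hybrid rep 1 (0.0848). In it the response regulator gene LOC_Os03g17570 (-0.89 ± 0.19, padj = 0.012) lost its call without Wufeng B rep 3 (0.063). KUN1 (3.53 ± 1.04, padj = 0.0482) was lost without hybrid rep 2 (0.144) or 3 (0.101) or Wufeng B rep 1 (0.112) or 3 (0.162). BBTI12 (LOC_Os01g04050, -4.58 ± 1.17, padj = 0.0288) was lost without hybrid rep 1 (0.0514), 2 (0.138) or 3 (0.0861) or Wufeng B rep 3 (0.356). OsMADS29 (-1.13 ± 0.28, padj = 0.0245) was lost without hybrid rep 2 (0.125) or 3 (0.0803) or Wufeng B rep 1 (0.1). The groups-only fit ended the calls of the glutelin gene (padj = 0.0906) and of every single gene given as lost in this comparison (0.125 to 0.239). Library totals ended B2-1 (0.0603) and KUN1 (0.059), the fit without a count filter KUN1 (0.0608) and a pseudocount of 0.1 BBTI12 (0.054).

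In total 2367 genes were called, 1319 higher and 1048 lower. Left out one at a time, hybrid reps 2 and 3 gave 512 and 1039, and Wufeng B reps 1, 2 and 3 gave 714, 5390 and 525. The groups-only fit gave 200 and DESeq2 4641. Library totals gave 560 higher and 802 lower, unscaled FPKM 1903 and 2714, and 21.4% of the rule's calls held under every alternative.

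Set against the mid-parent, the mean of both parents on the log2 scale, the hybrid at day 1 was higher in most ribosomal protein genes and in some starch synthesis and cell cycle genes. Ribosomal protein genes were higher in 104 and lower in 1 of 134 cases (112 and 3 within the list, median 0.78, padj = 1.78e-42, p_e = 0.771). S10 was higher by 1.79 ± 0.27, L32 by 1.60 ± 0.24 and S27 (LOC_Os04g32710) by 1.54 ± 0.15. Genes lower numbered 0 without Changhui rep 2 or 3, hybrid rep 2 or 3 or Wufeng B rep 1, and 2 without Wufeng B rep 2. Higher starch genes numbered 11 of 24, with 1 lower (13 and 2 within the list, median 0.47, padj = 0.000301, p_e = 0.771), 5 and 0 without hybrid rep 2 and 12 and 2 without Wufeng B rep 2. They included soluble starch synthase 2-3 (6.01 ± 1.22), starch synthase LOC_Os06g04200 (4.64 ± 1.24, padj = 0.0207), branching enzyme LOC_Os02g32660 (3.68 ± 0.85, padj = 0.00999) and the adenylyltransferase large subunit LOC_Os01g44220 (3.49 ± 0.80). Sucrose synthase LOC_Os07g42490 was higher by 5.17 ± 1.12. Without hybrid rep 2 the calls of LOC_Os06g04200 (0.0776) and LOC_Os02g32660 (0.058) were lost.

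Cell cycle genes were higher in 15 and lower in 3 of 62 cases (26 and 5 within the list, median 0.45, padj = 0.000195, p_e = 0.771), with MCM2 at 2.20 ± 0.49 (padj = 0.00828), lost without hybrid rep 2 (0.114). Without hybrid reps 1, 2 and 3 the list counts were 24 and 3, 6 and 0, and 12 and 1, without Wufeng B reps 1, 2 and 3 they were 12 and 1, 29 and 4, and 13 and 1, and without Changhui reps 1 and 2 they were 14 and 1, and 12 and 1. Core histones were higher in 14 of 51 cases (22 higher and 2 lower within the list, median 0.62, padj = 1.44e-05, p_e = 0.771). Genes higher numbered 1 and 3 without hybrid reps 2 and 3, 4 without Changhui rep 2, and 3, 32 (and 2 lower) and 9 without Wufeng B reps 1, 2 and 3. The core histone gene LOC_Os12g34510 (2.04 ± 0.60, padj = 0.0313) lost its call without hybrid rep 2 (0.202) or 3 (0.0725), Changhui rep 2 (0.0641) or Wufeng B rep 1 (0.0634).

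Storage proteins were higher in 3 of 40 cases (3 within the list, median 1.10, 1.04 at the bound, padj = 2.65e-05, p_e = 0.771), the glutelin gene LOC_Os02g15150 by 4.52 ± 0.87. Counts were 8 and 6 without Changhui reps 1 and 2, 1 without hybrid rep 2 or 3 and 6 without Wufeng B rep 2. Embryo and aleurone markers had 9 higher and 1 lower of 47 (9 and 2 within the list, median 0.74, 0.39 at the bound, FPKM 0.18, quantile 0.08, padj = 0.00365, p_e = 0.771). The call was lost on quantile values (0.122) and without hybrid rep 1 (0.127, 3 lower), with 4 and 0 without hybrid rep 2, 14 and 3 without Wufeng B rep 2, and 0 lower without Changhui rep 3, hybrid rep 3 or Wufeng B rep 1 or 3. KUN1 was higher by 4.63 ± 0.83, and RAL6 by 3.61 ± 0.92 (padj = 0.0166), lost without hybrid rep 3 (0.0851). Photosynthesis genes had a median of -1.15 (FPKM -0.76) with 0 of 68 called by edgeR, also within the list (padj = 2.04e-05, p_e = 0.787), and 1 and 2 lower without Changhui rep 2 and hybrid rep 1.

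Lower than the mid-parent were WRKY112 (-6.02 ± 0.90), the glycosyl hydrolase gene LOC_Os01g71380 (-5.81 ± 1.03), the response regulator gene LOC_Os03g17570 (-0.87 ± 0.17), ELF3 (-0.68 ± 0.18, padj = 0.021) and OsMADS29 (-0.94 ± 0.25, padj = 0.0196). Without hybrid rep 2 the calls of ELF3 (0.152) and OsMADS29 (0.134) were lost, and that of OsMADS29 without hybrid rep 3 (0.0775). The cycloartenol synthase gene LOC_Os11g35710 was at 0 in the hybrid, 25.4 ± 6.60 CPM in Wufeng B and 0.198 ± 0.342 in Changhui, a call (padj = 0.0147) lost without Changhui rep 3 (1) or hybrid rep 2 (0.0665). Kinesin-13A was higher by 0.39 ± 0.12 (padj = 0.039), lost without any library but Changhui rep 1, hybrid rep 1 and Wufeng B rep 2 (padj = 0.0652 to 0.289).

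Of single genes named in this comparison, S10, L32, S27, WRKY112 and LOC_Os01g71380 kept their calls in the groups-only fit, and all others lost theirs (padj = 0.0514 to 0.143). The linear mid-parent ended sucrose synthase (0.114), soluble starch synthase 2-3 (0.0814), LOC_Os06g04200 (0.145), LOC_Os02g32660 (0.0729) and the histone (0.0814), and the weighted one LOC_Os06g04200 (0.0574), Kinesin-13A (0.0605) and the histone (0.069). Library totals ended ELF3 (0.0666) and Kinesin-13A (0.102), unscaled FPKM Kinesin-13A (0.0674) and DESeq2 the cycloartenol synthase (0.0685).

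The comparison called 4283 genes, 2911 higher and 1372 lower, 1181 and 2672 without hybrid reps 2 and 3, 1400 in the groups-only fit and 6557 with DESeq2. Library totals gave 2370 higher and 758 lower, limma on log2(FPKM + 1) 2732 and 3037, unscaled FPKM 3001 and 2447, quantile values 3135 and 2351, a filter at a mean of 5 FPKM 2312 and 1787, and the log2 of the linear parental mean 2026 and 1607. With Wufeng B rep 2 and Changhui rep 3 both left out, a setting added after the data were seen, 6456 were called. Of the rule's calls, 19.7% held under every alternative.

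At day 1 the hybrid lay above both parents at 735 genes and below both at 260, where independent lists would give 144.7 and 68.5. Groups-only fits gave 4 and 3, library totals 235 and 120 and DESeq2 1333 and 815. At an unadjusted p below 0.05 in edgeR, 2125 and 1451 stood against 609.5 and 604 from independent lists and means of 79.1 and 143.2 in 20 simulated draws with no effect and shared hybrid libraries. Without hybrid reps 2 and 3 the counts above were 65 and 315, without Wufeng B reps 1, 2 and 3 they were 108, 2014 and 103, and without Changhui rep 2 454. Below both, hybrid reps 2 and 3 gave 26 and 88, Wufeng B reps 1, 2 and 3 gave 72, 616 and 65, and Changhui reps 1 and 2 gave 134 and 133. S10 and L32 were among the genes above both, and the response regulator gene LOC_Os03g17570 among those below both.

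At day 10 the hybrid differed from Changhui at fewer genes than at day 1. It had counts of the Wufeng B-side genes csAtPR5 (12 ± 1.41 CPM against 0, at least 124-fold), LOC_Os06g04399 (8.92 ± 7.64, at least 92.7-fold) and LOC_Os03g07270 (7.79 ± 4.90, at least 80.9-fold). A cinnamoyl CoA reductase gene (LOC_Os01g18110), of the lignin pathway, stood at 10.7 ± 7.24 CPM against 0 (at least 111-fold) and a transferase family gene (LOC_Os05g06380) at 10.3 ± 4.15 (at least 107-fold). Lower were the xylem cysteine proteinase 2 gene (LOC_Os05g01810, -3.29 ± 0.39), a sucrose transporter gene (LOC_Os03g07480, -1 ± 0.19), whose product moves sucrose across membranes, and the auxin-induced gene 5NG4 (LOC_Os05g33900, -2.37 ± 0.54, padj = 0.0257). A neutral invertase domain gene (LOC_Os02g34560) was higher by 0.63 ± 0.13 (padj = 0.0152). The 5NG4 call was lost without Changhui rep 3 (0.0901) or hybrid rep 1 (0.0662) or 2 (0.0648), and the invertase call without Changhui rep 1 (0.072) or 2 (0.0626) or hybrid rep 2 (0.0893). The groups-only fit ended both (0.0673 and 0.136), and unscaled FPKM (0.401) and library totals (0.365) the invertase call.

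Embryo and aleurone markers had a median of 0.64 (0.59 at the bound, totals 0.26, FPKM 0.25, padj = 0.0128, p_e = 0.771) with 0 of 47 called by edgeR, over all genes or within the list, and 1 and 3 higher without Changhui rep 2 and hybrid rep 3. The call was lost without Changhui rep 1 (0.0662) or hybrid rep 1 (0.0611) or 2 (0.127). In all 852 genes were called, 608 higher and 244 lower. Without Changhui reps 1 and 3 there were 432 and 393, and without hybrid reps 1, 2 and 3 476, 448 and 1442. The groups-only fit gave 454 and DESeq2 2165. Library totals gave 368 higher and 869 lower (median of all genes -0.31) and unscaled FPKM 247 and 698, and 37.5% of the rule's calls held under every alternative.

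Against Wufeng B at day 10 several storage protein genes were higher in the hybrid. The glutelin gene LOC_Os02g15150 stood at 27400 ± 5410 against 672 ± 123 CPM (5.35 ± 1.17, padj = 0.0162), PROLM27 was higher by 4.48 ± 0.95 (padj = 0.014) and PROLM12 by 2.14 ± 0.30. Without Wufeng B reps 1, 2 and 3 the glutelin call (0.0876, 0.0887 and 0.0646) and that of PROLM27 (0.0727, 0.0772 and 0.0635) were lost. Storage proteins had a median of 1.51 (totals 0.87, FPKM 0.72, quantile 0.59, padj = 2.17e-09, p_e = 0.771). Ribosomal protein genes (padj = 9.85e-14, p_e = 0.771) had a median of 0.41 that turned to -0.15 on library totals and -0.18 on unscaled FPKM (quantile 0.13). Ribosomal proteins S17 (LOC_Os04g52361, 6.04 ± 0.69) and L18a-1 (LOC_Os06g25294, 2.45 ± 0.23), MCM9 (2.91 ± 0.48, lost on unscaled FPKM, padj = 0.109, and quantile values, 0.0608), the acyl-CoA dehydrogenase domain gene LOC_Os06g23870 (7.79 ± 0.44) and OsFBX14 (9.57 ± 7.97 CPM against 0, at least 105-fold) were higher.

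The lipid transfer protein genes LTPL28 (LOC_Os03g59380, -3.14 ± 0.52) and LTPL124 (LOC_Os04g52260, -2.87 ± 0.54), a pathogenesis-related Bet v I gene (LOC_Os04g39150, -2.27 ± 0.39) and a beta-expansin gene (LOC_Os06g47360, -2.25 ± 0.44), of a family that loosens cell walls, were lower than in Wufeng B. The sucrose transporter LOC_Os03g07480 (-0.73 ± 0.19, padj = 0.0402) lost its call without any library but hybrid rep 3 (padj = 0.0533 to 0.105). Photosynthesis genes had a median of -0.80 (-0.75 at the bound, totals -1.43, quantile -0.45, padj = 0.000271, p_e = 0.797) with 0 of 68 called by edgeR, over all genes or within the list, and 1 higher without hybrid rep 3. The list call was lost on unscaled FPKM (0.963). The count was 1395, 950 higher and 445 lower. Without Wufeng B reps 1, 2 and 3 it was 540, 455 and 802, and without hybrid reps 1 and 2 643 and 869. The groups-only fit gave 2214 and DESeq2 2900. On library totals, with a median of all genes of -0.56, 512 were higher and 6140 lower, on unscaled FPKM 311 and 4917, with limma on log2(FPKM + 1) 842 and 668, and 42.1% of the rule's calls held under every alternative.

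Against the log2 mid-parent at day 10, most called genes were higher in the hybrid with TMM and lower on library totals. The xylem cysteine proteinase 2 gene stood at 2.81 CPM against 27.6 and 12.2 in Changhui and Wufeng B (-2.70 ± 0.36), and the sucrose transporter LOC_Os03g07480 was lower by -0.87 ± 0.17 (padj = 0.0148), lost without hybrid rep 1 (0.0634) or 2 (0.0598). The transferase family gene LOC_Os05g06380 and the cinnamoyl CoA reductase gene LOC_Os01g18110 stood at 10.3 ± 4.15 and 10.7 ± 7.24 CPM in the hybrid, 1.74 ± 0.461 and 2.56 ± 1.02 in Wufeng B and 0 in Changhui. PROLM12 was higher by 1.29 ± 0.24 (padj = 0.026), a dehydrin gene (LOC_Os11g26780), of a family of drought and seed maturation proteins, by 2.80 ± 0.70 (padj = 0.0494) and a core histone gene (LOC_Os09g39730) by 1.72 ± 0.38 (padj = 0.0256). Lower were 5NG4 (-1.94 ± 0.49, padj = 0.0455), the beta-expansin LOC_Os06g47360 (-1.64 ± 0.39, padj = 0.0369), an expansin (LOC_Os02g44108, -3.33 ± 0.75, padj = 0.0268) and a phytosulfokine precursor gene (LOC_Os07g03200, -1.20 ± 0.26, padj = 0.0222), a peptide growth factor.

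The calls of PROLM12, the dehydrin and 5NG4 were lost without any library but Changhui rep 2 and hybrid rep 3 (padj = 0.0656 to 0.132, 0.105 to 0.27 and 0.0523 to 0.146). The histone gene (0.0579 to 0.182) and the beta-expansin (0.0653 to 0.171) lost theirs without any library but Changhui rep 2, hybrid rep 3 and Wufeng B rep 3. The expansin lost its call without Changhui rep 1 (0.0569), hybrid rep 1 (0.0641) or 2 (0.101) or Wufeng B rep 1 (0.0555) or 2 (0.0597), and the phytosulfokine gene without hybrid rep 1 (0.122) or 2 (0.058) or Wufeng B rep 1 (0.0506). The linear mid-parent ended the calls of the transferase family gene (0.0721), the reductase (0.124), PROLM12 (0.11), the dehydrin (0.12), 5NG4 (0.0626), the histone (0.068) and the beta-expansin (0.0509). The dehydrin and 5NG4 were lost with the weighted one (0.0625 and 0.0584), without the count filter (0.0627 and 0.0564) and with a block (0.0925 and 0.0619). Quantile values ended PROLM12 (0.0718) and the beta-expansin (0.115), the groups-only fit the beta-expansin (0.0558), 3 limma settings the expansin (0.052 to 0.0727), and a filter at 5 FPKM (0.0583), DESeq2's size factors (0.0504) and library totals (0.0502) the dehydrin.

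Storage proteins had a median of 1.11 (totals 0.64, FPKM 0.44, quantile 0.29, padj = 2.59e-06, p_e = 0.771). Ribosomal protein genes (padj = 0.000284, p_e = 0.851) had a median of 0.18 that turned to -0.26 on library totals, -0.29 on unscaled FPKM and -0.03 on quantile values, and the call was lost without hybrid rep 1 (0.0579) or 3 (0.403), on unscaled FPKM (0.73) and quantile values (0.856). Embryo and aleurone markers had a median of 0.54 (0.44 at the bound, totals 0, FPKM 0, quantile 0.25, padj = 0.0142, p_e = 0.771), lost without hybrid rep 1 (0.0614) or 2 (0.191).

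The test called 814 genes, 668 higher and 146 lower. Without Changhui reps 1 and 3 there were 381 and 428, without hybrid reps 1 and 2 298 and 350, and without Wufeng B reps 1 and 2 385 and 347. The groups-only fit gave 1237 and DESeq2 1940. On library totals (median of all genes -0.43) 410 were higher and 3442 lower, and on unscaled FPKM 213 and 2828. The linear mid-parent, never below the log2 one, gave 196 (120 higher, 76 lower). Of the rule's calls, 3% held under every alternative.

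Above both parents at day 10 lay 65 genes and below both 38, where independent lists would give 21.4 and 4. The groups-only fit gave 18 below both, library totals 14 and 459 and DESeq2 231 and 191. The unadjusted counts were 619 and 539, against 277.6 and 181.3 from independent lists and simulated means of 115.3 and 246.4. With replicate number as a block 43 were above. Without Changhui reps 1, 2 and 3 the counts above were 11, 111 and 16, without hybrid reps 1, 2 and 3 10, 13 and 195, and without Wufeng B reps 1, 2 and 3 9, 8 and 29. Below both, Changhui reps 2 and 3 gave 73 and 23, hybrid reps 1, 2 and 3 gave 18, 25 and 114, and Wufeng B reps 1 and 2 gave 13 and 17. The sucrose transporter LOC_Os03g07480 lay below both parents.

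**Figure D3:**
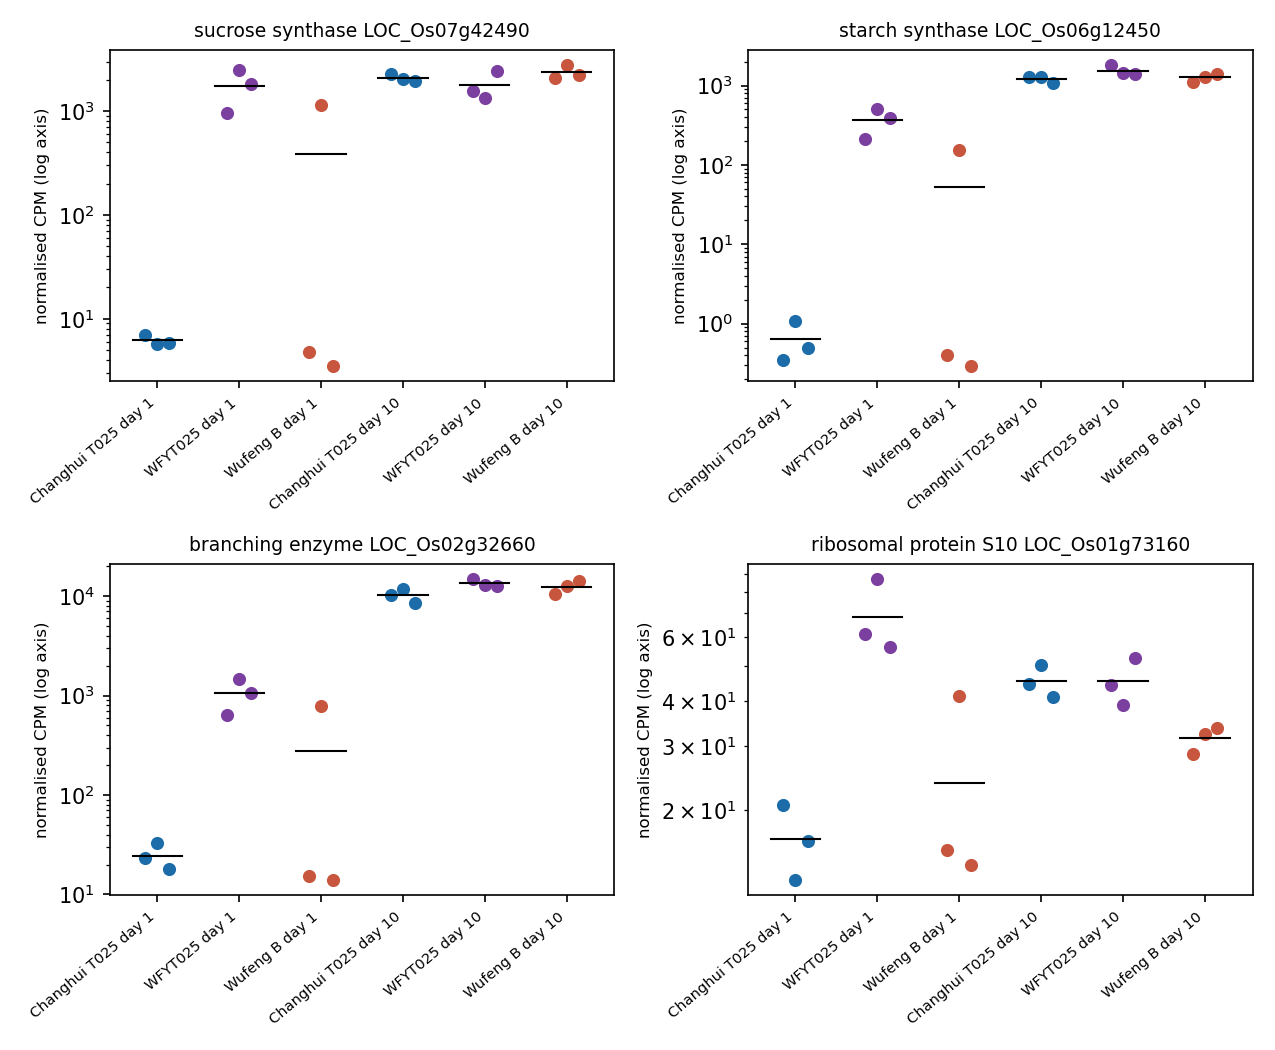
Normalised CPM of each library on a log axis, with a bar at the group mean, for sucrose synthase LOC_Os07g42490, starch synthase LOC_Os06g12450, branching enzyme LOC_Os02g32660 and ribosomal protein S10 LOC_Os01g73160. At day 1 sucrose synthase stood at 956, 2490 and 1820 CPM in the hybrid.

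A further test asked whether the hybrid's deviation from the mid-parent changed from day 1 to day 10. Its change had a median of -0.61 in ribosomal protein genes (totals -1.08, FPKM -1.12, padj = 3.78e-18, p_e = 0.771). S27 (-1.59 ± 0.22, padj = 0.00487), S10 (-1.52 ± 0.40, padj = 0.035) and L32 (-1.46 ± 0.36, padj = 0.0296) fell. Cyclin-dependent kinase B1-1 (-2.02 ± 0.41, padj = 0.0176) and an expansin gene (LOC_Os10g40730, -2.14 ± 0.38, padj = 0.0113) fell too, and a core histone gene (LOC_Os05g38640, 1.03 ± 0.23, padj = 0.0224) rose. S27 and the expansin kept their call under every alternative.

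Calls of these single genes were lost without hybrid day 1 rep 2 for S10 (0.124), L32 (0.109), B1-1 (0.0688) and the histone (0.0807), and without hybrid day 10 rep 2 likewise (0.0869, 0.0805, 0.0561 and 0.0815). Hybrid day 10 rep 1 ended those of S10 (0.0759), L32 (0.0594) and the histone (0.0806), and hybrid day 1 rep 3 (0.0525) and Changhui day 1 rep 2 (0.0562) that of S10. The weighted mid-parent ended S10 (0.0607) and L32 (0.053), and unscaled FPKM (0.0784) and library totals (0.0999) the histone. The list test passed also for cell cycle genes (median -0.33, totals -0.81, FPKM -0.74, padj = 0.00343, p_e = 0.771), core histones (-0.78, totals -1.28, FPKM -1.20, padj = 6.7e-05, p_e = 0.771) and starch synthesis genes (-0.36, totals -0.86, FPKM -0.90, quantile -0.66, padj = 0.00623, p_e = 0.771), the last lost without hybrid day 10 rep 3 (0.0556).

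THION3 (padj = 0.048) stood at 0 CPM in the hybrid at day 1 and 141 ± 53.6 at day 10, against 18.2 ± 4.68 and 52.6 ± 15.8 in Changhui and Wufeng B at day 10. A dehydrin gene (LOC_Os11g26760, padj = 0.0298) stood at 0.0218 ± 0.0378 and 5.06 ± 4.5 CPM in the hybrid. In genes with a falling deviation the Changhui mean rose, its SD near it at day 10 (LOC_Os04g49720 at 212, 4.3 and 150 CPM). In the hybrid they fell or, for a proteinase gene, hardly changed. They were the pectinesterase inhibitor genes LOC_Os04g49720 (hybrid 10.2 ± 6.02 to 0.937 ± 1.62, Changhui 0 to 122 ± 107 CPM, padj = 0.0409) and LOC_Os08g42890 (7.45 ± 2.96 to 0, 0.0322 ± 0.0294 to 47.7 ± 42.5, padj = 0.0332), and LTPL29 (LOC_Os01g58660, 7.23 ± 1.94 to 0.0305 ± 0.0528, 0 to 17.3 ± 15.1, padj = 0.025). LTPL36 (LOC_Os03g25350, 34.4 ± 10.6 to 0.0305 ± 0.0528, 0.726 ± 0.395 to 19.2 ± 16.8, padj = 0.0242), a gamma-thionin gene (LOC_Os02g07624, 2.71 ± 1.65 to 0.234 ± 0.317, 0 to 21.2 ± 18.1, padj = 0.0321) and a carboxyl-terminal proteinase gene (LOC_Os02g54960, 3.62 ± 1.91 to 3.37 ± 5.33, 0.013 ± 0.0225 to 84.4 ± 67.1, padj = 0.0468) followed.

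All 8 calls ended without hybrid day 1 rep 2 (padj = 0.074 to 0.13). They also ended without hybrid day 10 rep 1 (0.0684 to 0.117) or 2 (0.0772 to 0.112). Hybrid day 1 rep 3 ended those of the dehydrin (0.0708), LOC_Os04g49720 (0.0675), LOC_Os08g42890 (0.0583) and the gamma-thionin (0.0582). Changhui day 10 reps 1 and 3 and Wufeng B day 10 reps 1 and 2 ended LOC_Os04g49720 (0.0608 to 0.0635), LOC_Os08g42890 (0.0509 to 0.0529) and the gamma-thionin (0.0507 to 0.0529). Wufeng B day 10 rep 1 ended the dehydrin (0.05), Changhui day 1 reps 1 and 2 LOC_Os04g49720 (0.0528 and 0.0539) and hybrid day 10 rep 3 LOC_Os08g42890 (0.0515). THION3 was lost without any library but Changhui day 1 rep 1, hybrid day 10 rep 3 and those of Wufeng B at day 1 (0.0559 to 0.13). The proteinase was lost without any library but Changhui day 10 rep 2, hybrid day 1 rep 1, hybrid day 10 rep 3 and those of Wufeng B at day 1 (0.0573 to 0.122). THION3, LOC_Os04g49720 and the proteinase were lost without the count filter (0.0604, 0.0523 and 0.0587), with a block (0.0674, 0.062 and 0.0649) and with the linear mid-parent (0.0589, 0.0913 and 0.112), which ended LTPL29 (0.0644) and the gamma-thionin (0.0638) too. The weighted one ended LOC_Os04g49720 (0.0636) and the proteinase (0.0773), counts divided by 4 THION3 (0.0786) and 3 limma settings the dehydrin (0.0857 to 0.0937).

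The interaction count was 2067, 997 higher and 1070 lower, and 4390 with DESeq2. It was 1288 without Changhui day 1 rep 2, 1128 and 1240 without its day 10 reps 1 and 3, 216 and 875 without hybrid day 1 reps 2 and 3, and 387 and 294 without hybrid day 10 reps 1 and 2. Without Wufeng B day 1 reps 1 and 2 it was 1356 and 4238, and without its day 10 reps 1 and 2 1127 and 1071. Library totals gave 354 higher and 3502 lower and unscaled FPKM 656 and 4407, and 10.4% of the rule's calls held under every alternative.

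Other lists gave no call in any comparison. Amylases, which break down starch, changed from day 1 to day 10 by a median of 0.82 in the hybrid, with 10 genes higher and 4 lower of 17 (10 and 4 within the list, padj = 0.132), and by -1.21 on library totals. Expansins in the hybrid had 10 higher and 20 lower of 41 (10 and 20 within the list, median -1.28, -1.17 at the bound, padj = 0.196). Pollen and anther markers were nearest to a call between the parents at day 1, with 1 higher and 2 lower of 66 in Changhui (0 and 2 within the list, median 0.72, padj = 0.0503). The 3 grain size genes and the 2 endosperm regulators were too few for a list test.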

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

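The results here came up because a test of the difference between days passed its threshold. The splits of the libraries were planned, and of the tests in this part only library totals were chosen after the data were seen.

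The list test of the hybrid's deviation from the mid-parent between days passed for 4 lists. Medians went from 0.45 to 0 for cell cycle genes (change -0.33) and from 0.62 to -0.13 for core histones (-0.78). They went from 0.78 to 0.18 for ribosomal protein genes (-0.61) and from 0.47 to 0.22 for starch synthesis genes (-0.36), where library totals turn the day 10 medians to -0.26 and -0.24. All 4 list calls of camera ended with an estimated correlation (adjusted p = 0.771). Among single genes S27 (LOC_Os04g32710, -1.59), S10 (LOC_Os01g73160, -1.52), L32 (LOC_Os09g32500, -1.46), cyclin-dependent kinase B1-1 (LOC_Os01g67160, -2.02) and an expansin (LOC_Os10g40730, -2.14) fell and a core histone gene (LOC_Os05g38640, 1.03) rose.

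Genes off in some groups had fitted values of 8.66 for THION3 (LOC_Os06g31890), 5.95 for a dehydrin (LOC_Os11g26760), -12.76 and -17.93 for the pectinesterase inhibitors LOC_Os04g49720 and LOC_Os08g42890, -14.11 for LTPL29 (LOC_Os01g58660) and -10.60 for LTPL36 (LOC_Os03g25350). A gamma-thionin (LOC_Os02g07624) had -11.54 and a carboxyl-terminal proteinase (LOC_Os02g54960) -8.31. Fitted values against groups at 0 depend on the prior count and are no bounds.

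In all, 2067 genes differed between days, and 216 without hybrid day 1 replicate 2, 294 without hybrid day 10 replicate 2 and 4238 without Wufeng B day 1 replicate 2. Of 100 drawn splits only the real one gave as many (highest other 365). Most mix cultivars (median 0), so chance is not excluded for a hybrid effect. Maturity of the grains was not measured, so the design does not separate it from cultivar.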

How the results depend on the processing

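The alternatives chosen after the data were seen are counts divided by 4, library totals without TMM, omission of both Wufeng B day 1 replicate 2 and Changhui day 1 replicate 3, and list tests without each library. The rest were set beforehand, and each was run, except that a fit of only the groups compared is, for the interaction, the same fit. Causes of the changes below were not tested.

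Single genes changed sign in 10 cases. Kinesin-13A (LOC_Os05g06280), higher at day 10 under TMM, reversed on unscaled FPKM and on library totals to -0.25 and -0.30 in Changhui, -0.42 and -0.48 in Wufeng B, and -1.24 and -1.33 in the hybrid. Between the parents at day 1, sucrose synthase LOC_Os07g42490 reversed to 0.61 without both doubted libraries and to 0.57 without Wufeng B replicate 2, and soluble starch synthase 2-3 (LOC_Os06g12450) to 0.98 and 0.84. Leaving out each library in turn gave -6.54 to 0.57 and -6.96 to 0.84. Of 191 named gene results 118 kept direction and call under every alternative tried, and 54 lost the call without 1 library. Over all 650 called genes of the naming rule, 322 (49.5%) kept it. Fits of only the groups compared ended 39 of 177 named calls, hybrid day 1 replicate 2 left out 34 of 86, hybrid day 10 replicates 1 and 2 left out 21 and 23 of 63, and the linear mid-parent 17 of 45.

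List calls numbered 56 of 168. With an estimated correlation 0 remained by camera, the storage protein rise between days included, so that setting does not rank the lists. Leaving out 1 library gave 53 to 64. Those lost under other settings are given beside each list above.

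Counts kept within 1.5 times with DESeq2's size factors (16 of 16) and without the count filter (16 of 16). A replicate block moved 1 of 17, the genes above both parents at day 10, to 43. DESeq2 as the test gave 4117 and 4593 for the parents at day 1 and day 10, 7152 and 2165 for the hybrid against Changhui, 4641 and 2900 against Wufeng B, 6557 and 1940 against the mid-parent and 4390 for the interaction. With it 1333 genes lay above and 815 below both parents at day 1, and 231 and 191 at day 10. In fits of only the groups compared these were 1099 and 5210, 2890 and 454, 200 and 2214, and 1400 and 1237. Genes above and below both parents at day 1 were then 4 and 3, and 18 lay below both at day 10.

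A change of at least 2-fold left 1912 genes for the parents at day 10, 2680 for the hybrid against Changhui at day 1, 1378 and 914 against Wufeng B at day 1 and day 10, and 2085 and 532 against the mid-parent. It left 325 above and 86 below both parents at day 1 and 32 above at day 10. A filter at 5 FPKM gave 1590 for the parents at day 1 and 411 below both at day 1, and counts divided by 4 gave 415 and 24 below both at day 1 and day 10.

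For the hybrid against Wufeng B at day 1, limma gave 4375 on log2(FPKM + 1), 4337 without trend and robust variance, 4617 on unscaled FPKM, 4402 on quantile-normalised values and 3712 with a pseudocount of 0.1. In the same order the interaction gave 3187, 3160, 5063, 3237 and 3125, genes above both parents at day 1 1323, 1306, 1217, 1496 and 1261, and below both 684, 695, 532, 519 and 523. Genes above both at day 10 were 137, 134 and, on unscaled FPKM, 31, and those below both 286 on unscaled FPKM and 68 with the pseudocount of 0.1. Unscaled FPKM also gave 3730 for the parents at day 1 and 5228 and 3041 for the hybrid at day 10 against Wufeng B and the mid-parent. Quantile-normalised values gave 467 against the mid-parent at day 10, and its linear definition 196.

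On library totals the hybrid against Wufeng B gave 1362 at day 1 and 6652 at day 10, against the mid-parent at day 10 3852, and the interaction 3856, with 235 above and 120 below both parents at day 1 and 14 and 459 at day 10. Without both doubted libraries the hybrid at day 1 gave 6288 against Wufeng B and 6456 against the mid-parent, the interaction 4489, and 1940 above and 552 below both parents.

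Leaving out each library in turn gave 1552 to 2433 genes for the parents at day 1 and 1852 to 2361 at day 10. The hybrid gave 1743 to 4929 and 393 to 1442 against Changhui at day 1 and day 10, 512 to 5390 and 455 to 1442 against Wufeng B, and 1181 to 6281 and 298 to 1201 against the mid-parent. Changes between days gave 15748 to 16096 in Changhui, 14390 to 15983 in Wufeng B and 14158 to 14650 in the hybrid, and the interaction 216 to 4238. Above both parents lay 65 to 2014 at day 1 and 8 to 195 at day 10, and below both 26 to 616 and 13 to 114.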

Other observations

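Tests of developmental stage, scaling, doubted libraries and library identity below were chosen after the results were seen. So was the storage gene test's scale, library totals. The splits of libraries were planned.

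At day 1 the hybrid stood above the mid-parent in sucrose synthase LOC_Os07g42490, soluble starch synthase 2-3 and ribosomal protein genes. From day 1 to day 10 sucrose synthase rose in Changhui but stood at 1760 and 1780 CPM in the hybrid, and ribosomal medians were 0.80, 0.01 and -0.23 in Changhui, Wufeng B and the hybrid (-0.78, -1.50 and -2.24 on library totals), no common rise. Genes called against Changhui moved in the direction of Wufeng B's change from day 1 to day 10 in 67.3% of cases, where the product of both lists' shares gives 51.7% and all genes 61.8% (63.5% to 73.4% without 1 library). Against Wufeng B, with the change in Changhui, it was 68.2% against 51% and 60.6% (55.3%, without hybrid replicate 2, to 73%). For the parents at day 1, with the hybrid's change, it was 45%, where the product gives 50.2%. Hybrid grains further along in development are a candidate cause of the set. Scaling as the whole cause is argued against by 3128 genes on library totals (4283 with TMM). Counts outside both parents fell more there, so scaling stays open for them. Omitting the doubted libraries (6456 genes) decides nothing, as 1 stood near the hybrid. Genotype stays open, untested.

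Wufeng B day 1 replicate 2 stood with the hybrid libraries in starch and sucrose genes. Hybrid RNA would bring transcripts of 44 genes on in Changhui and the hybrid but off in Wufeng B at day 10, and their median there was 0 CPM, against 2.91, 3.75 and 2.86 in the hybrid libraries and 0 in both other Wufeng B libraries. Its difference from its group correlated with Changhui's change between days at r = 0.35 (0.35 by rank). Hybrid replicate 2 did so at 0.32 (0.392 by rank), so the 2 measures order these libraries differently and leave grains further along in development open as a cause.

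At day 10 the same measure gave 65.1% against Changhui (product 53.5%, all genes 50.8%, 61.9% to 68.8% without 1 library) and 73.9% against Wufeng B (52.6%, 56.6%, 68.6% to 75.1%), and 59.4% for the parents (50.2%). Later development of hybrid grains may thus contribute, although the parents' share lay above its product too. On library totals 410 genes were higher and 3442 lower than the mid-parent (median -0.43). With 62 storage and allergen genes left out, 392 were higher and 515 lower (43.2% higher, median -0.21). This removed most of the lower excess, but a share under 50% argues against those genes as the whole cause. Genotype (untested) and, for higher genes, the log2 mid-parent stay open.

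Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Real counts and the highest other were 2412 and 774 for the parents at day 1, 3013 and 0 at day 10, 4726 and 30 for the hybrid against Changhui at day 1, 852 and 119 at day 10, 2367 and 12 against Wufeng B at day 1 and 1395 and 1 at day 10. Between days they were 17171 and 2, 16168 and 0, and 15729 and 0, and the real split alone (1 of 10) reached its count in each case. Of 100 drawn splits, 1 reached the 4283 genes against the mid-parent at day 1, and the highest other gave 3927. That other split had Changhui replicate 3 and Wufeng B replicates 1 and 3 in the hybrid's place, the libraries with the highest photosynthesis shares of day 1. The 735 above both parents were reached by 1 (highest other 419), and the 260 below both by 5 (572). Fits of only the groups compared gave 1400 against the mid-parent and 4 above both parents. At day 10, 2 reached the 814 against the mid-parent (highest other 1984, with Wufeng B in the hybrid's place). The 65 above and 38 below both were reached by 2 each (174 and 559). Most splits mix cultivars (median 0), so chance is not excluded for a hybrid effect.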
